A study of Mus musculus with 35 samples.

How the data were processed

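RNA of sorted epithelial cells of mice was measured in 35 libraries of 13 groups. Per the labels' protocols, skin was digested overnight in trypsin, cells stained with antibodies were sorted into Trizol, and libraries were made with the SMARTer Stranded Total RNA-Seq Pico v2 kit, which starts from total RNA and keeps strand. The antibodies, aligner, counting program, annotation and use of strand are not given in the sources used here, so genes that overlap, stand antisense to each other or share reads with near-identical copies (the Hba, Sprr and H2 families among those named) are uncertain. The submitters' processing notes name the genome build mm10, and positions come from an annotation of that build.

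The authors deposited a table per library with a count of total reads, TPM and RPKM per gene. The counts are whole numbers and, per the file headers, total gene reads. The values show that the authors' counts hold exon and intron reads and that the TPM and RPKM deposited beside them rest on exon reads only. RPKM served only for this check and for intron shares, with exon reads taken as RPKM × exon length, scaled on genes without introns. List counts adjusted over the list alone are those higher, then those lower. Tables of the 18 back skin libraries list 53715 genes and those of the 17 tail, palate and tongue libraries 49585, with 47436 names in common, so the authors processed these sets differently. Of these names 51843 and 47102 were matched to the annotation. In the second set 4 features that take ribosomal RNA-like reads (Zc3h7a, Peak1, Filip1l and Gphn) held 9.39 to 19.8% of reads over all its libraries, against 0.0970 to 1.18% in back skin. No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom at least 23.1).

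Each comparison was tested on the deposited counts with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test after TMM scaling, with genes kept by filterByExpr (minimum count 10, minimum total 15) and Benjamini-Hochberg adjusted p under 0.05. Fits held the 18 back skin, 9 tail skin, 8 oral or 20 basal layer libraries, with group means only. The SE is the log2 fold change over the square root of F. CPM are scaled by TMM. A fold against a side with 0 reads used a floor of 3 reads per library, and one against 1 to 3 reads has a 95% counting interval. The 36 lists (606 genes) were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM (prior count 2), adjusted over the lists of a comparison. They cover cell cycle (mitosis, DNA replication, inhibitors), layers (basal, spinous, granular), hair follicle (bulge, upper follicle), tissue identity (Hox, oral transcription factors, oral keratins, tail scale), pathways (Wnt, BMP and TGF-β, Notch), metabolism and stress (cholesterol, oxidative phosphorylation, glycolysis, mitochondrial, ribosomal, clock, interferon, MHC class I, immediate early, wound), population and sort surface markers, and markers of 9 other cell types. Members were also adjusted over the list alone.

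Genes were named by a rule fixed before the data were examined. It takes the 10 largest rises and falls (5 for differences of LRC effects) among genes past the test with an average log2 CPM of at least 3 and, except for those differences, with every library of one side above every library of the other, without predicted, mitochondrial and ribosomal protein genes. It adds up to 4 members per list with the smallest p, and the population and sort surface markers. Of these genes, and of the list results, the text prints a part for length, and each list at least once. Some genes that the rule names are not reported here.

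Alternatives chosen before the data were examined were median-of-ratios scaling, DESeq2 1.42.0, no low-count filter, the replicate number as a block, other sets of libraries in the fit, each library left out in turn, bulge against LRC or nLRC alone, oral against tail or back alone, and camera with an estimated correlation and fry for lists. Chosen after seeing the data were limma on log2 of exon TPM plus 1 (genes with TPM of at least 1), fits without back bulge 2, palate nLRC 2 or tail bulge 3 where these lie outside the comparison, list medians under other scalings, lists of oral against each skin alone and of palate without nLRC 2, and spinous against basal within label classes.

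Every replicate number occurs in all groups of a tissue, but no label says what it stands for. Deviations from group means correlated between libraries of the same number at 0.233 to 0.322 for LRC and nLRC of back basal, 0.326 to 0.585 of tail and 0.163 to 0.291 of back spinous layer, 0.109 to 0.328 between spinous and basal and 0.151 to 0.324 between granular and spinous layer. All were over 0.1, so the numbers were taken to pair these libraries, though the main tests treat them as independent. On counts simulated from the real means, with 100 genes changed by 2 and 100 by 1 on the log2 scale, the tests recovered 75% and 5% in back basal, 99% and 18% in tail, 90% and 18% in palate, 92% and 16% in tongue and 74% and 3% in back spinous LRC comparisons, 90% and 9% and 100% and 37% for bulge in back and tail, 100% and 27% and 93% and 17% between layers, 100% and 57% for tongue against palate, 100% and 94% for oral against skin and 49% and 4% and 91% and 14% for differences of LRC effects. For tail LRC, DESeq2 and limma each recovered 99.5% of 200 genes changed by 2, and camera called a raised list and 0 of 39 unchanged ones.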

Results

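RNA was measured in 35 libraries of sorted epithelial cells from C57BL/6J mice 2 months old that carried K5-tTA and pTRE H2B-GFP. In this system cells with an active keratin 5 promoter make a histone-GFP fusion until doxycycline stops it, and the label is then diluted at each division. Cells that kept the label (label-retaining cells, LRC, called slow-cycling in the labels) and cells that had lost it (nLRC, fast-cycling) were sorted from the basal layer of back skin and tail skin (n = 3 libraries per group) and of palate and tongue (n = 2 per group), and from the spinous layer of back skin (n = 3 per group). The granular layer of back skin and the hair follicle bulge of back and tail skin, the niche of hair follicle stem cells, gave 3 libraries each. Doxycycline was given for 2 weeks in skin and for 10 days in the oral tissues. Reads assigned to genes numbered 9785944 to 20560481 per library in back skin, 8421582 to 14093720 in tail skin, 11680595 to 15641556 in palate and 11847897 to 13034075 in tongue. No label says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. Reads of Xist and Y-linked genes differed between replicate numbers in back and tail skin, so there the libraries of a group did not all come from the same animals. Back bulge library 2 held 9785944 reads, 34.5% of them on ribosomal RNA features, with a scaling factor of 0.50. Tail bulge library 3 held 31.3% on such features and 8421582 reads. The intron share of reads in the median gene was 6.13% in back bulge library 2. Gene values are log2 fold changes ± SE unless a fold or CPM (counts scaled to library size, mean ± SD) are given. Intervals and lower bounds cover counting error only. A ratio with an interval, given where a group had 0 reads, is that of mean to pooled CPM. Positions are on mm10.

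The series title sets slow-cycling against fast-cycling epidermal stem cells. In back skin basal layer, slow-cycling cells held more Igfbp3, a binding protein of insulin-like growth factors, and Skint7, a keratinocyte gene of the Skint family. They held less of 37 other genes, among them Igfbp2, the transglutaminase gene Tgm2 and complement C3. All 37 also fell in spinous LRC libraries, so sebaceous cells in the nLRC sort stay possible here. Igfbp3 (ENSMUSG00000020427.11, chromosome 11, 7206086 to 7213923) was 8.91-fold higher, at 288 ± 73.1 against 32.3 ± 7.73 CPM, in all 3 LRC against all 3 nLRC libraries (adjusted p = 0.0219, edgeR quasi-likelihood test, Benjamini-Hochberg), and Skint7 had 1.97 ± 0.30. Igfbp2 (ENSMUSG00000039323.18, chromosome 1, 72824503 to 72852474) was 109-fold lower, at 0.0771 ± 0.0214 CPM in LRC and 9.39 ± 6.89 CPM in nLRC libraries. In all 3 LRC libraries the next largest falls were Tgm2 (−4.78 ± 0.77), Lama4 (−4.40 ± 0.62), Avpr1a (−4.35 ± 0.84), Cd200 (−4.14 ± 0.81) and C3 (−3.86 ± 0.75). The ceramide synthase gene Cers4 (−3.68 ± 0.69), the cytochrome P450 gene Cyp1b1 (−3.57 ± 0.46), the RNA-binding protein gene Rbms3 (−3.56 ± 0.59) and the forkhead gene Foxc1 (−2.37 ± 0.47) also fell. Markers of sebocytes, the lipid-making cells of the sebaceous gland, stood lower with these genes (0 of 12 rose, 1 fell, 11 did neither, 0 and 7 adjusted over the list alone, camera lower, adjusted p = 2.2e-10, adjusted p = 0.485 with an estimated correlation). The member that passed was Mgst1 (−3.54 ± 0.66), while Pparg and Soat1 had −3.64 ± 0.87 and −3.60 ± 0.80. Hair follicle bulge genes (0 of 27 rose, 1 fell, 26 did neither, 0 and 5 adjusted over the list alone, camera lower, adjusted p = 2.7e-04) stood lower. So did upper follicle genes (0 of 13 past the test, 0 and 3 adjusted over the list alone, camera lower, adjusted p = 8.2e-04). DNA replication genes stood higher (0 of 30 past the test, 0 and 0 adjusted over the list alone, camera higher, adjusted p = 8.2e-04). For these there was no adjusted p below 0.662 with an estimated correlation. Of the markers used to tell the populations apart, Dlx1 had 1.23 ± 0.88 and Slc1a3 −0.57 ± 0.62, neither past the test. In all, 39 of 16574 genes passed, 2 higher and 37 lower. Other settings called 0 (limma on exon-only TPM) to 219 (DESeq2). Leaving out single libraries gave 3 without LRC 1, 3 without LRC 2, 2 without nLRC 2, 128 without back bulge 2, 5 without LRC 3 and 4 without nLRC 3.

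In slow-cycling cells of tail skin basal layer 14 of 28 measured hair follicle bulge genes rose and 0 fell, and 9 of 12 upper follicle genes rose. The homeobox genes Dlx3 and Msx2 and 6 of 22 genes of glycolysis and hypoxia fell. Adgrl3, an adhesion receptor gene (ENSMUSG00000037605.16, chromosome 5, 81020138 to 81825133), was 17.3-fold higher in all 3 LRC libraries (adjusted p = 1.9e-05, edgeR quasi-likelihood test). Lrig1 (ENSMUSG00000030029.14, chromosome 6, 94604529 to 94700158), an EGF receptor antagonist of the upper follicle, was 7.76-fold higher, at 109 ± 20.7 against 14.1 ± 2.00 CPM. Dlx3 (ENSMUSG00000001510.8, chromosome 11, 95120119 to 95125296) was 15.4-fold lower. Other large rises were Hmcn1 (3.92 ± 0.84), Pappa (3.91 ± 0.24), Lmcd1 (3.78 ± 0.62) and Dnm3 (3.69 ± 0.32). Other large falls were Krt90 (−3.92 ± 0.79), Hhip (−3.86 ± 0.67), Basp1 (−3.83 ± 0.49) and Susd4 (−3.37 ± 0.63), each in all 3 libraries. Among the bulge genes (14 of 28 rose, 0 fell, 14 did neither, 20 and 1 adjusted over the list alone, camera higher, adjusted p = 1.2e-11, adjusted p = 0.0268 with an estimated correlation) were the transcription factors Lhx2 (3.34 ± 0.33), Sox9 (2.52 ± 0.24) and Runx1 (2.70 ± 0.26) and the keratin gene Krt15 (1.99 ± 0.31). The upper follicle genes (9 of 12 rose, 0 fell, 3 did neither, 9 and 1 adjusted over the list alone, camera higher, adjusted p = 1.3e-06, adjusted p = 0.0901 with an estimated correlation) included Krt79 (2.46 ± 0.39), Atp6v1c2 (3.37 ± 0.34) and Cst6 (2.31 ± 0.34). The intron share of reads in the median gene with long introns was 45.9 ± 7.50% in LRC and 32.6 ± 8.55% in nLRC libraries (SD, n = 3 each). LRC 2 had 52.9% and 27652 genes with a read, other tail libraries 19726 to 23500. The mitosis genes (4 of 30 rose, 0 fell, 26 did neither, 11 and 0 adjusted over the list alone, camera higher, adjusted p = 5.6e-06, adjusted p = 0.723 with an estimated correlation) included Nusap1 (1.56 ± 0.37), Aurkb (1.5 ± 0.34) and Kif11 (1.45 ± 0.33), which act in the spindle and at cell division. Glycolysis and hypoxia genes (0 of 22 rose, 6 fell, 16 did neither, 0 and 13 adjusted over the list alone, camera lower, adjusted p = 5.6e-06), with Gapdh (−0.87 ± 0.21), Egln3 (−0.86 ± 0.19) and Pfkl (−0.79 ± 0.14), stood lower. So did the nuclear-encoded oxidative phosphorylation genes (0 of 24 rose, 1 fell, 23 did neither, 0 and 14 adjusted over the list alone, camera lower, adjusted p = 1.5e-07). For both there was no adjusted p below 0.611 with an estimated correlation. The oral transcription factor genes (0 of 4 rose, 3 fell, 1 did neither, 1 and 3 adjusted over the list alone, camera lower, adjusted p = 0.00612) gave Msx2 (−3.29 ± 0.32) and Dlx5 (−0.72 ± 0.16) beside Dlx3. The basal keratin, integrin and basement membrane genes (1 of 20 rose, 3 fell, 16 did neither, 1 and 4 adjusted over the list alone, camera lower, adjusted p = 0.00912) gave Krt14 (−1.32 ± 0.25), Krt5 (−1.08 ± 0.25) and Bcam (−0.99 ± 0.17). Neither list had an adjusted p below 0.203 with an estimated correlation. Sebocyte markers went both ways (1 of 12 rose, 3 fell, 8 did neither, 1 and 5 adjusted over the list alone, camera lower, adjusted p = 0.0447, adjusted p = 0.723 with an estimated correlation), with Soat1 (−2.97 ± 0.53), Far2 (−2.53 ± 0.62) and Scd1 (−1.60 ± 0.32) and with Acsbg1 (1.96 ± 0.21). In total, 690 of 14993 genes passed, 468 higher and 222 lower. The count was 446 by limma on exon-only TPM (78.0% higher, against 67.8%) and up to 2128 by other settings. It was 342 without nLRC 1, 434 without nLRC 2 and 345 without LRC 3.

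**Figure D1:**
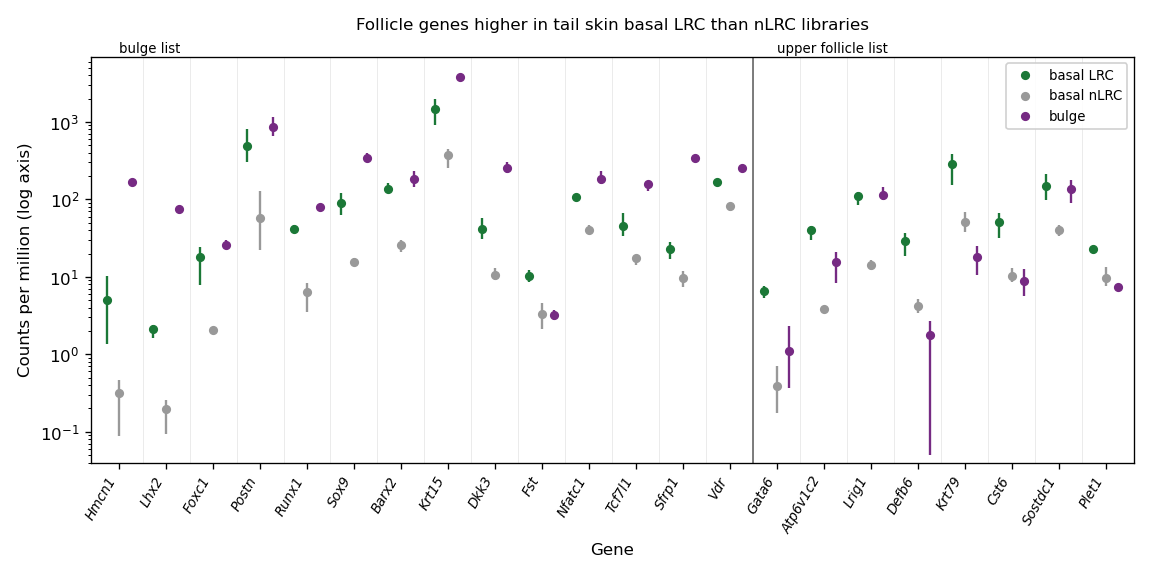
Mean CPM (log axis) of the bulge and upper follicle genes that rose in tail skin LRC libraries, in LRC, nLRC and bulge libraries (n = 3 each, bars from the lowest to the highest library, values under the lower axis limit drawn at it). Lrig1 reached 109 ± 20.7 CPM (mean ± SD) in LRC, 14.1 ± 2.00 in nLRC and 114 ± 25.7 in bulge libraries, and Krt79 283 ± 118, 51.5 ± 15.6 and 18 ± 7.20.

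In palate no gene separated slow- from fast-cycling cells past the test, with n = 2 libraries per group. Lists stood apart from other genes only at the preset correlation (no adjusted p below 0.808 with an estimated correlation): those of oxidative phosphorylation and cholesterol synthesis lower and that of mitosis higher in LRC libraries. The clock and bulge lists also stood higher. Here nLRC library 2 stood apart. Its intron share in the median gene was 3.36% (14.1 to 16.7% in the other 3 palate libraries) and its scaling factor 0.666. Without this library, in a test chosen after the data were seen, nLRC library 1 was alone in its group. The mitosis, clock, bulge and melanocyte lists then stayed higher and the cholesterol and oxidative phosphorylation lists lower. With 1 nLRC library this test cannot decide whether the calls hold. Oxidative phosphorylation genes (0 of 24 past the test, 0 and 0 adjusted over the list alone, camera lower, adjusted p = 2.0e-07) had the smallest p-values at Cyc1 (−0.92 ± 0.28) and Cycs (−0.88 ± 0.27). Cholesterol synthesis genes (0 of 22 past the test, 0 and 0 adjusted over the list alone, camera lower, adjusted p = 2.0e-07) had them at Sqle (−1.12 ± 0.30) and Msmo1 (−0.73 ± 0.26). With an estimated correlation no adjusted p of either was below 0.808. Mitosis genes stood higher (0 of 30 past the test, 0 and 0 adjusted over the list alone, camera higher, adjusted p = 3.9e-04), with Anln (1.01 ± 0.25) and Kif11 (0.69 ± 0.30). So did circadian clock genes (0 of 18 past the test, 0 and 0 adjusted over the list alone, camera higher, adjusted p = 0.00357), with Npas2 (0.89 ± 0.35). Next were hair follicle bulge genes (0 of 21 past the test, 1 and 0 adjusted over the list alone, camera higher, adjusted p = 0.00519), with Timp3 (1.67 ± 0.40) and Postn (1.42 ± 0.55). For these there was no adjusted p below 0.808 with an estimated correlation. Melanocyte markers, of another cell type, also stood higher (0 of 3 past the test, 1 and 0 adjusted over the list alone, camera higher, adjusted p = 0.0108, adjusted p = 0.808 with an estimated correlation), with Kit (1.24 ± 0.52) and Mitf (1.57 ± 0.51). The edgeR test called 0 of 14923 genes, 1082 had an unadjusted p under 0.05, DESeq2 called 12 and limma on exon-only TPM 0. Simulation with 1 spread for all genes recovered 90% of log2 changes of 2 and 18% of 1, so real ones may be missed. The count was 269 without the low-count filter and 1601 without nLRC library 1, which left nLRC library 2 alone in its group.

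In tongue, n = 2 libraries per group, slow-cycling cells held more of Col6a1, a collagen VI chain typical of fibroblasts, and no other gene passed. Col6a1 (ENSMUSG00000001119.7, chromosome 10, 76708792 to 76726168) was 21.4-fold higher, at 18.4 ± 2.63 against 0.846 ± 0.130 CPM (adjusted p = 0.0280, edgeR quasi-likelihood test). Lgr6, a Wnt pathway gene of epidermal stem cells, had −3.69 ± 0.44 and did not pass over all genes. Interferon response genes stood lower as a list in LRC libraries (0 of 18 past the test, 0 and 0 adjusted over the list alone, camera lower, adjusted p = 1.6e-04, adjusted p = 0.50 with an estimated correlation), with Gbp3 (−2.64 ± 1.03) and Oasl2 (−1.94 ± 0.77). Basal keratin, integrin and basement membrane genes stood higher (0 of 20 past the test, 0 and 0 adjusted over the list alone, camera higher, adjusted p = 0.00172, adjusted p = 0.424 with an estimated correlation), with Krt15 (0.79 ± 0.31) and Cav1 (0.59 ± 0.18). Fibroblast markers, of another cell type, stood higher (1 of 5 rose, 0 fell, 4 did neither, 2 and 1 adjusted over the list alone, camera higher, adjusted p = 0.00449, adjusted p = 0.424 with an estimated correlation). The median of the 9 tested by DESeq2 was −0.82. Wnt pathway genes stood lower (0 of 22 past the test, 0 and 4 adjusted over the list alone, camera lower, adjusted p = 0.0217, adjusted p = 0.50 with an estimated correlation), with Notum (−3.82 ± 0.96), Tcf7 (−1.37 ± 0.34) and Axin2 (−1.15 ± 0.25). Their median relative to all genes was 0.00 on exon-only TPM. Ribosomal protein genes stood higher (0 of 24 past the test, 0 and 0 adjusted over the list alone, camera higher, adjusted p = 0.00936, adjusted p = 0.702 with an estimated correlation). 1 of 14923 genes passed and 696 had an unadjusted p under 0.05. By edgeR 0 passed without LRC 1, LRC 2, nLRC 1 or nLRC 2 and 45 without palate nLRC 2, while 88 passed by DESeq2, 236 without the low-count filter and 6 when only these groups were fitted.

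In back skin spinous layer, LRC and nLRC libraries differed at 2571 of 16574 genes. In LRC libraries 13 of 20 spinous and 9 of 29 granular differentiation genes rose. Of mitosis genes 21 of 30 fell, of sebocyte genes 10 of 12 and of cholesterol synthesis genes 15 of 22. Igfbp3 was 11.2-fold higher, at 121 ± 54.1 against 10.9 ± 7.83 CPM, in all 3 LRC against all 3 nLRC libraries (adjusted p = 3.7e-04, edgeR quasi-likelihood test). Pparg (ENSMUSG00000000440.12, chromosome 6, 115360951 to 115490399), the lipid-regulating nuclear receptor of sebocytes, was 145-fold lower, at 1.92 ± 1.88 CPM in LRC and 282 ± 117 CPM in nLRC libraries. Lcn2, a defence gene with 0 reads in LRC libraries, was at least 30.0-fold lower. Large rises in all 3 libraries were Tmprss11f (3.19 ± 0.69), Krt78 (2.99 ± 0.67), Skint7 (2.93 ± 0.31) and Nptx1 (2.79 ± 0.47). Large falls were Dusp4 (−6.97 ± 1.05), Acoxl (−6.88 ± 1.02), Cers4 (−6.86 ± 0.78), Tgm2 (−6.54 ± 0.76) and C3 (−6.35 ± 0.83). Mitosis genes stood lower (1 of 30 rose, 21 fell, 8 did neither, 1 and 25 adjusted over the list alone, camera lower, adjusted p = 1.3e-10, adjusted p = 0.514 with an estimated correlation), with Cenpf (−3.15 ± 0.60), Mki67 (−2.93 ± 0.57) and Tpx2 (−2.39 ± 0.43). The DNA replication genes (0 of 30 rose, 6 fell, 24 did neither, 0 and 17 adjusted over the list alone, camera lower, adjusted p = 1.4e-06, adjusted p = 0.567 with an estimated correlation) gave Dut (−1.64 ± 0.39) and Rrm2 (−1.51 ± 0.46). Sebocyte markers, of another cell type, stood lower (0 of 12 rose, 10 fell, 2 did neither, 0 and 10 adjusted over the list alone, camera lower, adjusted p = 1.3e-10, adjusted p = 0.247 with an estimated correlation), with Mgst1 (−6.77 ± 0.72), Soat1 (−6.75 ± 0.85) and Far2 (−5.17 ± 0.67) beside Pparg. The cholesterol synthesis genes (3 of 22 rose, 15 fell, 4 did neither, 3 and 16 adjusted over the list alone, camera lower, adjusted p = 2.3e-06, adjusted p = 0.514 with an estimated correlation) included Lss (−2.20 ± 0.31). Melanocyte markers (0 of 8 rose, 1 fell, 7 did neither, 0 and 3 adjusted over the list alone, camera lower, adjusted p = 0.0105), with Kit (−4.40 ± 0.99), stood lower. So did the upper hair follicle genes (0 of 13 rose, 7 fell, 6 did neither, 0 and 9 adjusted over the list alone, camera lower, adjusted p = 3.1e-04), with Plet1 (−2.27 ± 0.44), Gata6 (−2.09 ± 0.50) and Lrig1 (−1.14 ± 0.21). Of the pair no list had an adjusted p below 0.461 with an estimated correlation. Spinous genes (13 of 20 rose, 0 fell, 7 did neither, 15 and 1 adjusted over the list alone, camera higher, adjusted p = 1.6e-08), with Krtdap (1.99 ± 0.38), Dsg1a (1.86 ± 0.28) and Sbsn (1.76 ± 0.24), stood higher. So did granular genes (9 of 29 rose, 0 fell, 20 did neither, 9 and 0 adjusted over the list alone, camera higher, adjusted p = 3.1e-04), with Spink5 (1.96 ± 0.20), Cers3 (1.61 ± 0.28) and Casp14 (1.54 ± 0.29). For both there was no adjusted p below 0.134 with an estimated correlation. The nuclear-encoded oxidative phosphorylation genes (0 of 24 rose, 11 fell, 13 did neither, 0 and 18 adjusted over the list alone, camera lower, adjusted p = 2.6e-07, adjusted p = 0.514 with an estimated correlation) stood lower, with Atp5b (−1.32 ± 0.26). Mitochondrially encoded mRNA made up 0.311 ± 0.0348% of reads in LRC and 0.638 ± 0.255% in nLRC libraries, and the intron share in the median gene with long introns was 59.4 ± 1.59% and 49.0 ± 7.15% (SD, n = 3 each). The fast-cycling marker Slc1a3, a glutamate transporter gene, fell by 3.98 ± 0.70 in the slow- and fast-cycling population marker genes (0 of 9 rose, 4 fell, 5 did neither, 0 and 5 adjusted over the list alone, camera lower, adjusted p = 0.0116, adjusted p = 0.333 with an estimated correlation). In the cell cycle inhibitor genes (3 of 17 rose, 1 fell, 13 did neither, 3 and 1 adjusted over the list alone, camera higher, adjusted p = 0.853, median, mean and test of unlike sign), Cdkn2b (2.01 ± 0.48) and Cdkn1a (1.14 ± 0.24) rose and Cdkn2c (−1.51 ± 0.41) fell. The Notch pathway genes (2 of 12 rose, 3 fell, 7 did neither, 3 and 3 adjusted over the list alone, camera higher, adjusted p = 0.637) gave Notch2 (1.01 ± 0.19) and Lfng (−1.85 ± 0.44). The 37 genes lower in basal LRC libraries were all lower here as well, against 3.19 by chance over 16574 genes, and 2 of 2 higher ones were higher here, against 0.138. Of 455 genes higher in tail basal LRC libraries and tested here 127 were lower in spinous LRC libraries, against 42.5 by chance, and 52 were higher, against 34.9. Of 212 lower in tail LRC libraries 41 were lower here too, against 19.8, and 24 higher, against 16.2. These comparisons share no library, though the replicate numbers pair those of back skin. The calls were 1141 higher and 1430 lower (44.4% higher, against 28.5% on exon-only TPM). Other settings gave 1065 by limma on exon-only TPM and 3895 when only these groups were fitted. Leaving out single libraries gave 1503 without LRC 1, 1683 without LRC 2, 1306 without nLRC 2 and 4476 without back bulge 2.

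**Figure D2:**
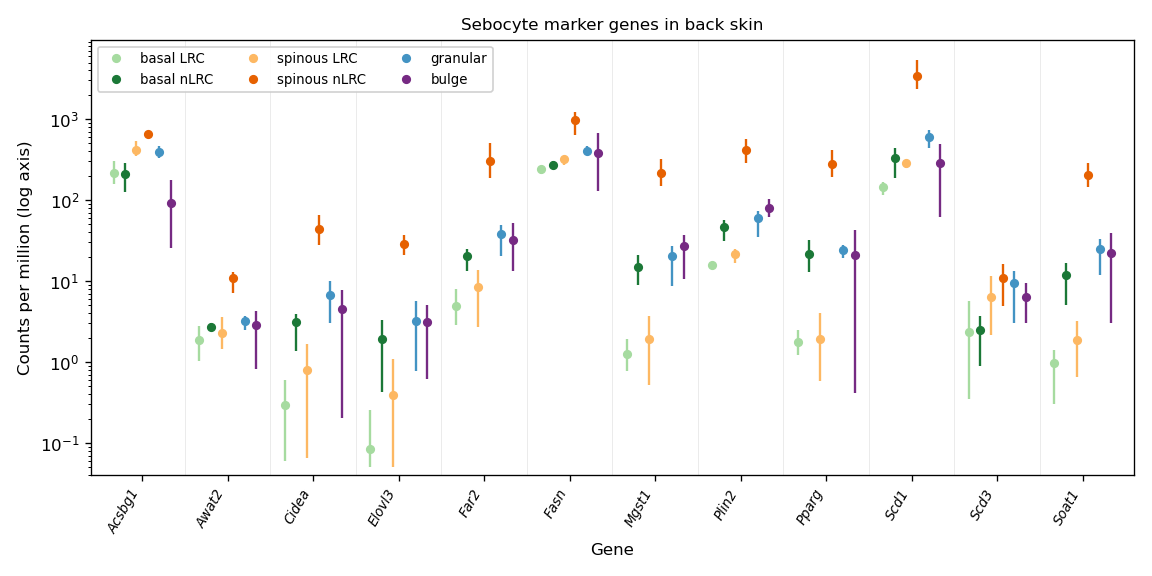
Mean CPM (log axis) of the 12 sebocyte marker genes in the 6 back skin groups (n = 3 libraries each, bars from the lowest to the highest library, values under the lower axis limit drawn at it). Pparg reached 282 ± 117 CPM (mean ± SD) in spinous nLRC, 21.6 ± 9.93 in basal nLRC, 1.92 ± 1.88 in spinous LRC and 1.74 ± 0.676 in basal LRC libraries.

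The series also sets epidermal stem cells against hair follicle stem cells. In back skin, 24 of 27 measured bulge genes were higher and 0 lower in bulge than in basal layer libraries. Bulge libraries also held more of 9 of 9 endothelial, 8 of 9 fibroblast and 8 of 8 melanocyte markers, and less Ly6a, the Sca-1 antigen of epidermal cells. Cd34 (ENSMUSG00000016494.9, chromosome 1, 194938819 to 194961279), a bulge surface marker commonly used to sort these cells, was 2982-fold higher, at 396 ± 294 against 0.153 ± 0.188 CPM (n = 3 bulge and 6 basal libraries, adjusted p = 3.7e-08, edgeR quasi-likelihood test). A gene used in a gate is no finding, and the gate is not known here. Tgm3 (ENSMUSG00000027401.9, chromosome 2, 130012349 to 130050399), a transglutaminase of the cornified envelope, was 87.0-fold lower, in all 3 bulge libraries. Higher in all 3 were Shisa2 (9.82 ± 0.51), Chat (9.28 ± 0.82), Aqp1 (9.17 ± 0.88), Serpinb11 (9.10 ± 0.76) and Tbx1 (8.93 ± 0.70). Lower were Bmpr1b (−6.29 ± 0.97), Pls1 (−6.23 ± 0.59), Il20ra (−5.81 ± 0.58) and Bmp3 (−5.66 ± 0.60). The bulge list (24 of 27 higher, 0 lower, 3 did neither, 25 and 0 adjusted over the list alone, camera higher, adjusted p = 2.7e-18, adjusted p = 0.0284 with an estimated correlation) included Lgr5 (8.56 ± 0.67), Lhx2 (6.77 ± 0.50) and Dkk3 (4.46 ± 0.31). The upper follicle genes (9 of 13 higher, 0 lower, 4 did neither, 9 and 0 adjusted over the list alone, camera higher, adjusted p = 1.4e-04) included Krt17 (4.40 ± 0.40) and Fst (4.57 ± 0.54). The BMP and TGF-β pathway genes (13 of 19 higher, 2 lower, 4 did neither, 14 and 2 adjusted over the list alone, camera higher, adjusted p = 2.2e-06) included Ltbp2 (6.12 ± 0.50) and Id4 (3.17 ± 0.29). For these last there was no adjusted p below 0.149 with an estimated correlation. All 9 endothelial markers were higher (9 of 9 higher, 0 lower, 0 did neither, 9 and 0 adjusted over the list alone, camera higher, adjusted p = 2.5e-11, adjusted p = 0.149 with an estimated correlation), with Cdh5 (9.29 ± 0.88), Vwf (8.60 ± 0.53) and Pecam1 (5.96 ± 0.56). Emcn, with 1 read in the basal libraries, was 1393-fold (95% counting interval 250.0 to 55020) higher. The fibroblast genes (8 of 9 higher, 0 lower, 1 did neither, 8 and 0 adjusted over the list alone, camera higher, adjusted p = 9.7e-05) gave Col6a2 (6.98 ± 0.87) and Vim (4.42 ± 0.54). The melanocyte genes (8 of 8 higher, 0 lower, 0 did neither, 8 and 0 adjusted over the list alone, camera higher, adjusted p = 1.1e-04) gave Tyrp1 (6.17 ± 0.73), Dct (5.73 ± 0.87) and Kit (4.88 ± 0.67). Neither list had an adjusted p below 0.257 with an estimated correlation. The mitosis genes (17 of 30 higher, 0 lower, 13 did neither, 21 and 0 adjusted over the list alone, camera higher, adjusted p = 0.00319) included Plk1 (2.31 ± 0.53) and Cdk1 (1.91 ± 0.48). Spinous genes stood lower (2 of 20 higher, 8 lower, 10 did neither, 2 and 10 adjusted over the list alone, camera lower, adjusted p = 0.0166), with Dsg1a (−2.08 ± 0.26) and Pkp1 (−1.37 ± 0.25), while Calml3 (6.89 ± 0.41) and Sbsn (1.94 ± 0.19) were higher. For these lists there was no adjusted p below 0.528 with an estimated correlation. In the sort surface marker genes (1 of 3 higher, 2 lower, 0 did neither, 1 and 2 adjusted over the list alone, camera lower, adjusted p = 0.710, median, mean and test of unlike sign), Ly6a (−4.06 ± 0.60) and Itga6 (−1.07 ± 0.22) were lower and Cd34 higher. In all, 4353 of 16574 genes passed, 2594 higher and 1759 lower (59.6% higher, against 47.8% on exon-only TPM). The number called was 1928 by limma on exon-only TPM, 2769 when only these groups were fitted and 2728 against nLRC alone.

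In tail skin (n = 3 bulge and 6 basal libraries), 25 of 28 bulge genes were higher in bulge libraries and 1 lower. Lower were 25 of 30 genes of mitosis and 13 of 20 of the spinous layer, and 9 of 9 endothelial markers were higher. Cd34 was 713-fold higher, at 150.5 ± 40.3 against 0.238 ± 0.313 CPM (adjusted p = 4.6e-07, edgeR quasi-likelihood test). Krt8 (ENSMUSG00000049382.10, chromosome 15, 101996698 to 102004482), a simple epithelial keratin gene, was 250.1-fold (95% counting interval 154 to 438) higher, with 16 basal reads. Grem1, a secreted BMP antagonist gene with 2 reads in the basal libraries, was 2487-fold (95% counting interval 688 to 20533) higher. Tmprss4, a membrane serine protease gene, was 51.7-fold lower. Higher in all 3 bulge libraries were Scrg1 (8.72 ± 0.33), Ctgf (8.28 ± 0.21), Pdlim3 (8.28 ± 0.59), Sema3e (7.78 ± 0.36) and Ppp1r3b (7.72 ± 0.25). Lower were Efemp1 (−5.58 ± 0.48), Slc16a9 (−5.50 ± 0.37), Foxq1 (−5.42 ± 0.43), Wnt3 (−5.39 ± 0.44) and Calm5 (−5.34 ± 0.64). The bulge list (25 of 28 higher, 1 lower, 2 did neither, 26 and 1 adjusted over the list alone, camera higher, adjusted p = 3.1e-18, adjusted p = 0.00793 with an estimated correlation) gave Lhx2 (6.80 ± 0.18), Lgr5 (5.76 ± 0.42) and Sfrp1 (4.51 ± 0.18). The BMP and TGF-β pathway genes (12 of 19 higher, 1 lower, 6 did neither, 12 and 1 adjusted over the list alone, camera higher, adjusted p = 1.2e-04) included Ltbp2 (7.30 ± 0.35) and Id4 (3.40 ± 0.32). The Hox genes (11 of 29 higher, 2 lower, 16 did neither, 13 and 2 adjusted over the list alone, camera higher, adjusted p = 2.9e-04) included Hoxd10 (2.18 ± 0.13) and Hoxd11 (1.79 ± 0.15). For these last there was no adjusted p below 0.0807 with an estimated correlation. Upper follicle genes went both ways (3 of 12 higher, 5 lower, 4 did neither, 3 and 7 adjusted over the list alone, camera lower, adjusted p = 0.199), with Krt17 (3.82 ± 0.31) and Lrig1 (1.54 ± 0.16) higher and Krt79 (−2.72 ± 0.37) and Plet1 (−1.02 ± 0.20) lower. Against basal LRC libraries alone Lrig1 had 0.065, so its rise was over nLRC libraries. Mitosis genes (0 of 30 higher, 25 lower, 5 did neither, 0 and 29 adjusted over the list alone, camera lower, adjusted p = 1.7e-09), with Mki67 (−2.31 ± 0.27), Cenpf (−1.96 ± 0.38) and Aspm (−1.91 ± 0.47), stood lower. So did DNA replication genes (0 of 30 higher, 12 lower, 18 did neither, 1 and 17 adjusted over the list alone, camera lower, adjusted p = 1.5e-05), with Pola1 (−1.15 ± 0.16). With an estimated correlation no adjusted p of either was below 0.560. The spinous layer genes (2 of 20 higher, 13 lower, 5 did neither, 3 and 14 adjusted over the list alone, camera lower, adjusted p = 7.3e-08) gave Krt1 (−5.06 ± 0.34), Krt10 (−5.03 ± 0.19) and Dsc1 (−3.79 ± 0.20). The granular layer genes (1 of 20 higher, 10 lower, 9 did neither, 2 and 10 adjusted over the list alone, camera lower, adjusted p = 1.6e-05) gave Casp14 (−4.90 ± 0.29) and Krt2 (−4.73 ± 0.49) and, higher, Spink5 (3.62 ± 0.28). Of the pair no list had an adjusted p below 0.0631 with an estimated correlation. Endothelial markers (9 of 9 higher, 0 lower, 0 did neither, 9 and 0 adjusted over the list alone, camera higher, adjusted p = 8.3e-07), with Cdh5 (6.20 ± 0.91) and Vwf (5.78 ± 0.67), were higher. So were fibroblast markers (6 of 7 higher, 0 lower, 1 did neither, 6 and 0 adjusted over the list alone, camera higher, adjusted p = 1.6e-05), with Col6a2 (6.61 ± 0.38) and Col1a1 (6.03 ± 0.42). For both there was no adjusted p below 0.0670 with an estimated correlation. In total, 3693 of 14993 genes passed, 2136 higher and 1557 lower. Higher calls were 57.8% of them, and 37.1% of 3151 on exon-only TPM.

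Between the layers of back skin, spinous libraries held more of 18 of 22 cholesterol synthesis and 10 of 20 spinous genes than basal libraries. They held less of 15 of 20 basal keratin, integrin and basement membrane genes and 16 of 30 DNA replication genes (n = 6 libraries of 3 replicate numbers on each side). Krt79 (ENSMUSG00000061397.8, chromosome 15, 101929332 to 101940324), a keratin gene of the infundibulum and sebaceous duct, was 15-fold higher in all 6 spinous libraries, at 633 ± 381 against 41.4 ± 24.6 CPM (adjusted p = 1.7e-05, edgeR quasi-likelihood test). Adgrf5, an adhesion receptor gene, was 17.2-fold lower. Other genes higher in all 6 were Cst6 (3.61 ± 0.39), Defb6 (3.48 ± 0.42), Sprr1a (3.40 ± 0.39), Alox12e (3.15 ± 0.34) and Myo5b (2.99 ± 0.42). Lower in all 6 were Col6a1 (−2.73 ± 0.48), Thbs2 (−2.46 ± 0.37), Ngfr (−2.40 ± 0.33) and Phldb2 (−2.29 ± 0.34). Cholesterol synthesis genes were higher as a group (18 of 22 higher, 0 lower, 4 did neither, 20 and 0 adjusted over the list alone, camera higher, adjusted p = 2.0e-21, adjusted p = 0.0711 with an estimated correlation), with Sqle (2.31 ± 0.30) and Lss (1.74 ± 0.22). The basal list stood lower (0 of 20 higher, 15 lower, 5 did neither, 0 and 16 adjusted over the list alone, camera lower, adjusted p = 1.9e-19, adjusted p = 0.0309 with an estimated correlation), with Itga3 (−1.94 ± 0.23), Krt14 (−1.62 ± 0.23), Krt5 (−1.49 ± 0.28) and Itgb4 (−1.29 ± 0.17). Spinous genes were higher (10 of 20 higher, 0 lower, 10 did neither, 12 and 0 adjusted over the list alone, camera higher, adjusted p = 3.1e-10, adjusted p = 0.0369 with an estimated correlation), with Calml3 (2.45 ± 0.34), Dsc1 (2.11 ± 0.33) and Sbsn (1.96 ± 0.17). The DNA replication genes (0 of 30 higher, 16 lower, 14 did neither, 0 and 27 adjusted over the list alone, camera lower, adjusted p = 6.5e-17) included Mcm6 (−1.39 ± 0.22) and Pole (−1.25 ± 0.27). The Wnt pathway genes (1 of 24 higher, 10 lower, 13 did neither, 2 and 11 adjusted over the list alone, camera lower, adjusted p = 1.4e-05) included Ccnd1 (−2.05 ± 0.21), Wnt10a (−1.60 ± 0.16) and Lgr6 (−1.45 ± 0.23) and, higher, Nkd2 (2.76 ± 0.36). Neither list had an adjusted p below 0.111 with an estimated correlation. Sebocyte markers were higher too (9 of 12 higher, 0 lower, 3 did neither, 12 and 0 adjusted over the list alone, camera higher, adjusted p = 3.1e-10), with Far2 (2.35 ± 0.43), Mgst1 (2.21 ± 0.45) and Scd1 (2.17 ± 0.38). So were the upper hair follicle genes (7 of 13 higher, 1 lower, 5 did neither, 9 and 1 adjusted over the list alone, camera higher, adjusted p = 2.3e-07), with Krt17 (1.62 ± 0.34) beside Krt79, Cst6 and Defb6. With an estimated correlation no adjusted p of either was below 0.105. Tested within label classes after the data were seen, sebocyte genes were higher in nLRC libraries (10 of 12, camera higher, adjusted p = 2.4e-15, adjusted p = 0.0563 with an estimated correlation), while in LRC libraries 0 of 12 passed (adjusted p = 0.0779). Of cholesterol genes 16 and 4 were higher in nLRC and LRC libraries, of spinous genes 3 and 12, and of DNA replication genes 0 and 19 were lower. In all, 1504 of 16574 genes passed, 812 higher and 692 lower. Other settings gave 599 (exon-only TPM) to 2736.

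Against the spinous layer of back skin, 13 of 29 granular genes were higher in granular libraries and 0 lower, 6 of 20 spinous genes were higher, and 10 of 20 basal keratin, integrin and basement membrane genes were lower (n = 3 granular and 6 spinous libraries). Sytl2 (ENSMUSG00000030616.15, chromosome 7, 90302252 to 90410719), a vesicle transport gene, was 14.1-fold higher in all 3 granular libraries, at 18.2 ± 6.21 against 1.29 ± 0.657 CPM (adjusted p = 4.8e-04, edgeR quasi-likelihood test). The stress keratin gene Krt6a was 11.6-fold higher. Cysltr1, a leukotriene receptor gene, was 6.23-fold lower. Also higher in all 3 were Sprr1a (3.47 ± 0.39), Cst6 (3.16 ± 0.42), Shisa2 (2.96 ± 0.45), Gsdma (2.96 ± 0.44), Krt23 (2.93 ± 0.57), Klk7 (2.93 ± 0.67) and Cdsn (2.87 ± 0.50). Lower were Dlk2 (−2.62 ± 0.48) and Ackr3 (−2.36 ± 0.54). The granular list (13 of 29 higher, 0 lower, 16 did neither, 23 and 0 adjusted over the list alone, camera higher, adjusted p = 2.0e-16, adjusted p = 0.0940 with an estimated correlation) included Ivl (2.71 ± 0.37) and Spink5 (1.74 ± 0.16) beside Klk7 and Cdsn. The spinous list (6 of 20 higher, 0 lower, 14 did neither, 14 and 0 adjusted over the list alone, camera higher, adjusted p = 1.5e-13, adjusted p = 0.0222 with an estimated correlation) included Dsc1 (2.34 ± 0.37), Calml3 (2.30 ± 0.36) and Sbsn (1.63 ± 0.19). The basal list (0 of 20 higher, 10 lower, 10 did neither, 0 and 13 adjusted over the list alone, camera lower, adjusted p = 1.6e-12), with Itga3 (−1.96 ± 0.30), Lamb3 (−1.90 ± 0.31) and Krt5 (−1.78 ± 0.36), stood lower. So did the DNA replication genes (0 of 30 higher, 4 lower, 26 did neither, 0 and 14 adjusted over the list alone, camera lower, adjusted p = 1.6e-12), with Dut (−2.06 ± 0.38) and Cdt1 (−1.99 ± 0.48). Of the pair no list had an adjusted p below 0.0683 with an estimated correlation. Langerhans cell and macrophage markers, of other cell types, stood higher as a list (1 of 10 higher, 0 lower, 9 did neither, 6 and 0 adjusted over the list alone, camera higher, adjusted p = 7.5e-07), with Epcam (1.48 ± 0.18). The erythroid genes (2 of 4 higher, 0 lower, 2 did neither, 2 and 0 adjusted over the list alone, camera higher, adjusted p = 0.0267) gave Hba-a1 (4.28 ± 1.11) and Hba-a2 (1.51 ± 0.37). For both there was no adjusted p below 0.0683 with an estimated correlation. The wound keratinocyte genes (3 of 12 higher, 1 lower, 8 did neither, 5 and 2 adjusted over the list alone, camera higher, adjusted p = 0.0126, adjusted p = 0.272 with an estimated correlation) hold Krt6a and Sprr1a. In total, 664 of 16574 genes passed, 409 higher and 255 lower. This became 1197 with the replicate number as a block, 1218 by DESeq2, 197 by limma on exon-only TPM and 1555 when only these groups were fitted. Leaving out single libraries gave 291 without granular 1, 288 without granular 2, 1590 without bulge 2, 379 without spinous LRC 3 and 330 without granular 3.

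The oral tissues share the doxycycline time and the processing. Tongue basal cells held more of the homeobox genes Tlx1 and Nkx2-3, of the hard keratins Krt84, Krt35 and Krt36 and of 8 of 18 granular layer genes. Palate cells held more Tfap2b, Eya1 and Eya4 and more of 12 of 30 DNA replication and 7 of 13 mitochondrially encoded genes (n = 4 libraries each). Nkx2-3 (ENSMUSG00000044220.13, chromosome 19, 43612325 to 43615892) was 174-fold (95% counting interval 84.5 to 433) higher in all 4 tongue libraries, at 22.6 ± 3.87 against 0.107 ± 0.214 CPM, with 7 reads in 1 palate library (adjusted p = 1.1e-04, edgeR quasi-likelihood test). Tlx1, with 0 reads in palate, was at least 65.7-fold higher in tongue, and Krt84, with 2 reads in palate, 916-fold (95% counting interval 254 to 7565) higher. In palate, Tfap2b was 1155-fold (95% counting interval 395 to 5599.8) higher, with 3 reads in tongue, and Eya1 (ENSMUSG00000025932.14, chromosome 1, 14168954 to 14310235), an eye and branchial arch developmental gene, 375-fold higher. Also higher in tongue were Tbx3 (4.64 ± 0.36), Cpn1 (4.63 ± 0.32), Slc25a21 (4.00 ± 0.70) and Pax9 (3.73 ± 0.38). Higher in palate were Eya4 (−9.56 ± 0.40), Iqgap2 (−6.71 ± 0.45), Slc38a4 (−6.66 ± 0.36) and Pdzrn3 (−6.34 ± 0.40), each in all 4 libraries. Granular genes (8 of 18 higher, 0 lower, 10 did neither, 14 and 0 adjusted over the list alone, camera higher, adjusted p = 2.8e-08), with Alox12b (4.24 ± 0.72), Elovl4 (3.24 ± 0.37), Rptn (3.19 ± 0.50) and Tgm1 (2.35 ± 0.24), were higher in tongue. So were spinous genes (7 of 20 higher, 0 lower, 13 did neither, 7 and 0 adjusted over the list alone, camera higher, adjusted p = 0.0300), with Dsc1 (1.83 ± 0.33) and Sbsn (1.45 ± 0.20). Neither list had an adjusted p below 0.561 with an estimated correlation. DNA replication genes (0 of 30 higher, 12 lower, 18 did neither, 0 and 20 adjusted over the list alone, camera lower, adjusted p = 7.6e-09), with Mcm2 (−0.91 ± 0.14), Lig1 (−0.91 ± 0.14) and Pcna (−0.80 ± 0.16), stood lower. So did mitochondrially encoded genes (0 of 13 higher, 7 lower, 6 did neither, 0 and 12 adjusted over the list alone, camera lower, adjusted p = 8.5e-08), with mt-Nd5 (−0.96 ± 0.17) and mt-Nd6 (−0.95 ± 0.14). With an estimated correlation no adjusted p of either was below 0.360. The slow- and fast-cycling population marker genes (1 of 8 higher, 5 lower, 2 did neither, 1 and 5 adjusted over the list alone, camera lower, adjusted p = 0.00220, adjusted p = 0.360 with an estimated correlation) included Dlx1 (−3.61 ± 0.55), Lgr6 (−2.43 ± 0.29), Slc1a3 (−1.88 ± 0.23) and Krt14 (−1.75 ± 0.31) and, higher, Lrig1 (1.27 ± 0.20). Going both ways were the tail scale genes (4 of 8 higher, 3 lower, 1 did neither, 4 and 3 adjusted over the list alone, camera higher, adjusted p = 0.346), with Krt36 (6.10 ± 0.67) and, by ratio, Krt35 (64.5, 27.7 to 199). Skeletal muscle markers, of the tissue under the epithelium, also went both ways (1 of 3 higher, 2 lower, 0 did neither, 1 and 2 adjusted over the list alone, camera lower, adjusted p = 0.156). The myosin gene Myh2, with 1 read in tongue, was 84.6-fold (95% counting interval 15.2 to 3341) higher in palate, and Tnni2 (1.20 ± 0.29) was higher in tongue. In all, 1436 of 14923 genes passed, 733 higher in tongue and 703 in palate (51.0% higher, against 64.1% on exon-only TPM). Elsewhere the count was 2453 without the low-count filter and 588 by limma on exon-only TPM. By library it was 3406 without palate nLRC 1, 913 without palate LRC 2, 892 without tongue LRC 1, 735 without tongue nLRC 1, 846 without tongue LRC 2 and 700 without tongue nLRC 2.

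Oral and skin basal layers differed at 8807 of 17103 genes. Oral libraries held the oral keratins Krt13 and Krt4 and the transcription factors Sox2, Pitx1 and Pax9. Skin libraries held more of 23 of 31 Hox genes, Gata3 and the spinous keratin Krt1 (n = 8 oral and 12 skin libraries). Doxycycline time differs in the same way, and so does the authors' processing for back skin, so the tissue cannot be told apart from them over all skin, while tail skin shares the oral processing. Krt13 (ENSMUSG00000044041.4, chromosome 11, 100117327 to 100121566) was 15710-fold higher in all 8 oral libraries, at 4418 ± 3462 against 0.234 ± 0.210 CPM (adjusted p = 5.4e-14, edgeR quasi-likelihood test). Sox2 (ENSMUSG00000074637.7, chromosome 3, 34650405 to 34652461), with 0 reads in skin, was at least 239-fold higher. Gata3 (ENSMUSG00000015619.10, chromosome 2, 9857078 to 9890034), an epidermal and hair follicle transcription factor gene, was 4256-fold (95% counting interval 2378 to 8525) lower, at 0.158 ± 0.211 against 528 ± 465 CPM. Hoxb6 and Hoxb8, with 0 reads in oral libraries, were at least 87.2-fold and at least 48.4-fold lower. Also higher in all 8 oral libraries were Krt4 (12.11 ± 0.48) and, by ratio, Chil4 (4315, 2412 to 8644), Pitx1 (1776, 1109.5 to 3049), Sim2 (1420.4, 887 to 2438) and Pax9 (2402, 1166 to 5974). Lower in all 8 were Krt1 (−9.46 ± 0.37) and, by ratio, Clca3a2 (6014, 3646 to 10745), Satb1 (387, 260.2 to 604) and Hoxa3 (204, 117 to 396). The Hox list (0 of 31 higher, 23 lower, 8 did neither, 0 and 23 adjusted over the list alone, camera lower, adjusted p = 9.2e-26, adjusted p = 9.9e-04 with an estimated correlation) kept its call against tail skin alone. There 0 were higher and 30 lower (camera lower, adjusted p = 1.3e-35, adjusted p = 4.2e-04 with an estimated correlation). So did the oral transcription factor genes (12 of 14 higher, 0 lower, 2 did neither, 12 and 0 adjusted over the list alone, camera higher, adjusted p = 2.7e-12, adjusted p = 9.9e-04 with an estimated correlation). Against tail they had 10 higher and 1 lower (camera higher, adjusted p = 2.7e-13, adjusted p = 6.0e-04 with an estimated correlation). A further such list was the oral keratin and cornified envelope genes (14 of 20 higher, 1 lower, 5 did neither, 15 and 1 adjusted over the list alone, camera higher, adjusted p = 1.9e-07, adjusted p = 0.0279 with an estimated correlation), with Krt6a (7.20 ± 0.28). Against tail they had 12 higher and 2 lower (camera higher, adjusted p = 3.9e-09, adjusted p = 0.0120 with an estimated correlation). Merkel cell markers were higher (5 of 6 higher, 0 lower, 1 did neither, 5 and 0 adjusted over the list alone, camera higher, adjusted p = 2.6e-04, adjusted p = 0.0343 with an estimated correlation), with Piezo2 (4.05 ± 0.47). Against tail they had 5 higher and 0 lower (camera higher, adjusted p = 4.8e-05, adjusted p = 0.0157 with an estimated correlation). Against back skin alone the oral keratin and Merkel lists lost the call with an estimated correlation (adjusted p = 0.0714 and 0.0727). Sox2 and Isl1 stand in the Merkel list and in an oral one. Other lists moved with the skin they were set against. MHC class I genes stood lower over all skin (0 of 10 higher, 10 lower, 0 did neither, 0 and 10 adjusted over the list alone, camera lower, adjusted p = 3.6e-04, adjusted p = 0.390 with an estimated correlation), with H2-Q4 (−2.13 ± 0.16) and Nlrc5 (−1.89 ± 0.28). Against tail alone 7 were higher and 0 lower (camera higher, adjusted p = 0.00111, adjusted p = 0.496 with an estimated correlation), where H2-Q4 had 0.98 and Nlrc5 1.79. Interferon response genes were not called over all skin (4 of 22 higher, 7 lower, 11 did neither, 4 and 8 adjusted over the list alone, camera lower, adjusted p = 0.425). Against tail 13 stood higher and 1 lower (camera higher, adjusted p = 1.3e-04, adjusted p = 0.496 with an estimated correlation). Against back 1 stood higher and 16 lower (camera lower, adjusted p = 5.9e-04, adjusted p = 0.485 with an estimated correlation). Mitochondrially encoded genes stood higher (12 of 13 higher, 0 lower, 1 did neither, 12 and 0 adjusted over the list alone, camera higher, adjusted p = 3.7e-08, adjusted p = 0.324 with an estimated correlation). Against tail 4 were higher and 0 lower (camera higher, adjusted p = 0.198), where mt-Nd6 (3.07 ± 0.10) turned to −0.13. Immediate early genes stood lower (1 of 25 higher, 19 lower, 5 did neither, 1 and 20 adjusted over the list alone, camera lower, adjusted p = 2.2e-05, adjusted p = 0.476 with an estimated correlation), with Egr2 (−5.45 ± 0.47) and Fosb (−4.62 ± 0.41). Against tail 5 were higher and 12 lower (camera lower, adjusted p = 0.159). Mitochondrially encoded mRNA was 0.464 ± 0.199% of reads in the 18 back, 1.0 ± 0.237% in the 9 tail, 1.45 ± 0.211% in the 4 palate and 1.07 ± 0.131% in the 4 tongue libraries. The T cell genes (0 of 4 higher, 2 lower, 2 did neither, 0 and 2 adjusted over the list alone, camera lower, adjusted p = 0.106) gave Thy1 (−2.12 ± 0.12). All other genes named for oral against skin kept their direction and call against tail skin alone. The calls were 4412 higher and 4395 lower, against tail skin alone 2553 and 3080, and against back skin alone 5059 and 5415. On exon-only TPM 14.2% of 12113 calls were higher against 50.1%, with the median gene at −0.64.

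The skins, processed differently, differed in LRC effect past the test. Bulge and upper follicle genes went higher with label retention in tail skin relative to back skin, 11 of 28 and 9 of 13 past the interaction test and 0 the other way. Mt4, Dlx3 and Procr went the other way (n = 6 libraries per skin). The LRC effect on Lrig1 was more positive in tail by 3.30 ± 0.29 (adjusted p = 1.0e-05, edgeR quasi-likelihood test), with 109 ± 20.7 and 14.1 ± 2.00 CPM in tail LRC and nLRC and 241 ± 20.2 and 309 ± 44.6 CPM in back, 3 libraries each. Gpc3 (ENSMUSG00000055653.13, chromosome X, 52272426 to 52613950), a glypican gene, had a difference of 6.11 ± 1.32. Procr (ENSMUSG00000027611.12, chromosome 2, 155751117 to 155755471), the endothelial protein C receptor gene, had −4.73 ± 1.02. Other effects more positive in tail were Hmcn1 (6.03 ± 1.13), Irx1 (5.77 ± 0.90), Arhgap24 (5.74 ± 0.54) and Adgrl3 (5.65 ± 0.94). More negative were Npr3 (−4.68 ± 0.57), Mettl7a3 (−4.25 ± 0.64), Mt4 (−4.14 ± 0.49) and Dlx3 (−3.94 ± 0.75). The bulge list (11 of 28 more positive, 0 more negative, 17 did neither, 17 and 1 adjusted over the list alone, camera higher, adjusted p = 3.6e-14, adjusted p = 0.0185 with an estimated correlation) included Foxc1 (5.50 ± 0.94), Sox9 (4.22 ± 0.44) and Barx2 (3.43 ± 0.59) beside Hmcn1. The upper follicle list (9 of 13 more positive, 0 more negative, 4 did neither, 10 and 1 adjusted over the list alone, camera higher, adjusted p = 1.4e-10, adjusted p = 0.0185 with an estimated correlation) included Krt79 (3.81 ± 0.54), Sostdc1 (3.29 ± 0.40) and Atp6v1c2 (3.21 ± 0.47) beside Lrig1. Mitosis genes (1 of 30 more positive, 0 more negative, 29 did neither, 15 and 0 adjusted over the list alone, camera higher, adjusted p = 4.6e-08) gave Aurkb (2.15 ± 0.47). Glycolysis and hypoxia genes (0 of 21 more positive, 1 more negative, 20 did neither, 0 and 7 adjusted over the list alone, camera lower, adjusted p = 4.8e-08) gave Slc16a3 (−2.50 ± 0.48). Of the pair no list had an adjusted p below 0.482 with an estimated correlation. In total, 463 of 17103 genes passed, 360 more positive in tail and 103 more negative. Other settings gave up to 1182. Other splits of back libraries alone gave 97 to 373, so tail may bring much of it.

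**Figure D3:**
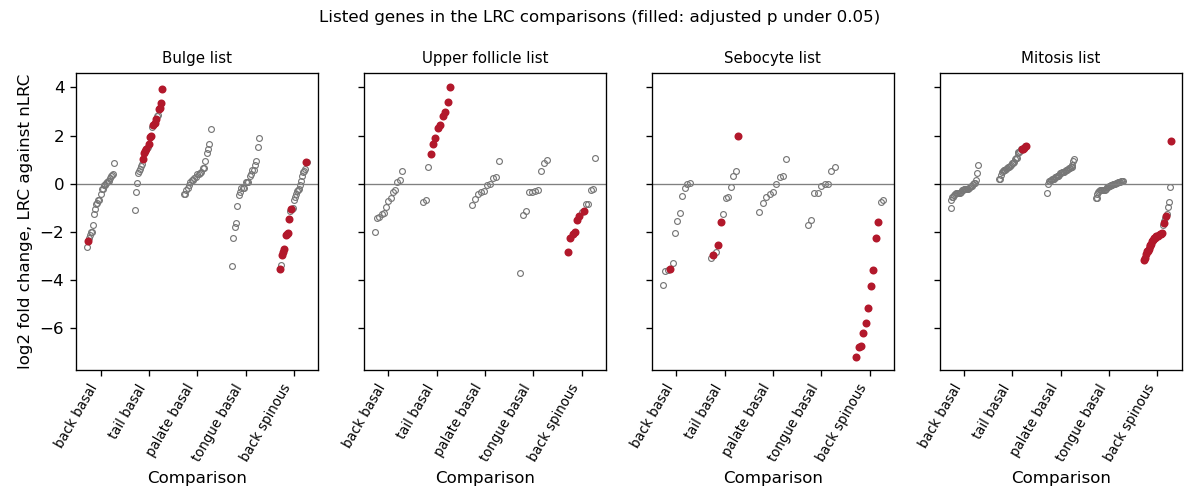
Fitted log2 fold change (LRC against nLRC) of each measured gene of 4 lists in 5 LRC comparisons, with filled points for genes past the test and open points for the others. Of bulge genes 0 of 27 rose and 1 fell in back basal, 14 of 28 rose and 0 fell in tail and 1 of 27 rose and 9 fell in back spinous comparisons, and of sebocyte genes 0 of 12 rose and 1 fell, 1 of 12 rose and 3 fell and 0 of 12 rose and 10 fell.

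Between oral epithelium and skin the LRC effect differed at 31 genes. It was more positive in the oral tissues for Igfbp2 and for Soat1 and Far2, lipid enzyme genes of sebocytes, and more negative for Pitx1, Pdzrn3 and Lgr6 (n = 8 oral and 12 skin libraries). Doxycycline time differs likewise and cannot be told apart from tissue. Chance was not excluded (13 of 100 splits as large). Igfbp2 had a difference of 3.54 ± 0.67 (adjusted p = 0.0384, edgeR quasi-likelihood test). Pitx1 (ENSMUSG00000021506.7, chromosome 13, 55825051 to 55836192), a homeobox gene of oral epithelium and hindlimb, had −3.92 ± 0.71, with 17 reads in skin. Others were Soat1 (3.41 ± 0.59), Far2 (3.17 ± 0.57), Tmem176b (2.66 ± 0.31) and Atp1b1 (2.65 ± 0.51) in the positive and Pdzrn3 (−3.38 ± 0.62), Il20ra (−2.95 ± 0.37) and Apcdd1 (−2.27 ± 0.40) in the negative direction. DNA replication genes stood lower as a list (0 of 30 past the test, 0 and 0 adjusted over the list alone, camera lower, adjusted p = 4.7e-05, adjusted p = 0.738 with an estimated correlation). In the upper hair follicle genes (0 of 13 more positive, 2 more negative, 11 did neither, 0 and 4 adjusted over the list alone, camera lower, adjusted p = 5.2e-05), Lgr6 (−2.15 ± 0.39) and Lrig1 (−1.28 ± 0.23) passed. In the sebocyte genes (2 of 12 more positive, 0 more negative, 10 did neither, 2 and 0 adjusted over the list alone, camera higher, adjusted p = 9.2e-05) it was Soat1 and Far2. For both there was no adjusted p below 0.214 with an estimated correlation. Of the endothelial markers, of another cell type, Pecam1 (−2.36 ± 0.45) passed (0 of 8 more positive, 1 more negative, 7 did neither, 0 and 1 adjusted over the list alone, camera lower, adjusted p = 0.0743). Of 17103 genes 17 were more positive and 14 more negative, 54.8% positive, against 71.4% on exon-only TPM and 38.5% with all 35 libraries in the fit. Other settings called 13 to 361. Leaving out single libraries gave 20 without back LRC 1, 20 without back nLRC 2, 16 without tail nLRC 1, 20 without palate LRC 1, 10 without palate nLRC 1 and 17 without palate LRC 2. It was 12 without tongue LRC 1, 7 without tongue nLRC 1, 9 without tongue LRC 2 and 12 without tongue nLRC 2.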

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

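The tests of cell mixtures and intron reads and the splits that keep tail groups whole were chosen after the results were seen, and the other splits and the test without back bulge 2 before. The LRC effect differed past the interaction test between tail and back skin at 463 genes. Those named had log2 differences of Lrig1 3.30, Gpc3 6.11, Hmcn1 6.03, Irx1 5.77, Arhgap24 5.74, Adgrl3 5.65, Foxc1 5.50, Sox9 4.22, Barx2 3.43, Krt79 3.81, Sostdc1 3.29, Atp6v1c2 3.21 and Aurkb 2.15 and, the other way, Procr −4.73, Npr3 −4.68, Mettl7a3 −4.25, Mt4 −4.14, Dlx3 −3.94 and Slc16a3 −2.50. Between oral tissues and skin 31 genes differed, those named by Igfbp2 3.54, Soat1 3.41, Far2 3.17, Tmem176b 2.66 and Atp1b1 2.65 and by Pitx1 −3.92, Pdzrn3 −3.38, Il20ra −2.95, Apcdd1 −2.27, Lgr6 −2.15, Lrig1 −1.28 and Pecam1 −2.36.

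Other splits of the same samples into groups of the same sizes were tested, with sides of several groups fitted as 1 group. For LRC against nLRC the 10 possible splits are too few for a share under 0.05. The real split gave 39 against 0 genes in the highest other in back basal, 690 against 0 in tail and 2571 against 0 in back spinous layer (in each 1 of 10 as large), so the others that part all 3 pairs also gave 0. Shares were under 0.05 for bulge in back (1 of 84, 4359 against 289) and tail (1 of 84, 2808 against 269). So they were for spinous against basal (1 of 100, 901 against 403) and tongue against palate (1 of 35, 1321 against 1). Oral against skin had 1 of 100 (4948 against 1051). Libraries of the same number were moved as if independent, so these shares may be too small. Granular against spinous (3 of 84, 115 against 3101) stays open, since the 3 spinous nLRC libraries set apart gave 3101. For differences in LRC effect, most splits drawn break the tail groups, removing the tail effect (1 of 100 as large in tail minus back, 4 of 100 in oral minus skin). Of splits that keep them whole, the 20 in tail minus back are too few for a share under 0.05 (463 against 373, 1 as large). In oral minus skin 13 of 100 drawn were as large (31 against 131), so chance was not excluded.

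Bulge and upper follicle genes were higher in tail LRC libraries. Intron reads are argued against, since 18 of 22 called members kept the call on exon TPM. Of upper follicle genes 7 of 9 were higher in LRC than in bulge libraries (bulge minus LRC: Krt79 −3.95, Gata6 −2.68). For these it argues against bulge cells in the LRC sort. For bulge genes they cannot be told apart from a change in the basal LRC cells themselves: 108 bulge-enriched genes outside the lists reached a median of 4.64% of the bulge excess (quartiles 1.60 to 13.2%) and 26 bulge members, called or not, 13.7% (2.64 to 44.0%), ranges too wide to decide. The sources give no gate. Upper follicle cells in the sort were not tested.

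Sebocyte genes were lower in back spinous LRC libraries. Intron reads are argued against, since 10 of 10 called members kept the call on exon TPM. Sebaceous cells in the nLRC sort may bring these genes: the nLRC excess in the basal layer was a median of 6.47% of that in the spinous layer and near 1 ratio in all 10 members (4.72 to 9.63%), against quartiles of 8.78 to 29.4% over 1171 other genes. Their most abundant members, Scd1 and Fasn, are used by other epidermal cells too. A difference between slow- and fast-cycling spinous cells stays open.

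Endothelial genes were higher in back bulge libraries. Back bulge 2 alone is argued against, since all 9 were called without it. Endothelial cells in the sort may bring them, as all 9 were highest in bulge 1 and bulge 3 held a median ratio of 0.368 of that (quartiles 0.326 to 0.404), against 0.789 (0.699 to 1.56) over 24 bulge genes. Cd34, the usual bulge antigen, is also made by endothelium, and no gate against endothelial cells is named. Expression in the bulge cells stays open.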

How the results depend on the processing

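Settings chosen after the data were seen are named with the methods. Ranges over single libraries aside, counts of calls named here moved by over 1.5 times unless said otherwise, and the cause was not tested. Without the low-count filter they were back basal LRC 180, tail LRC 2128, palate LRC 269, tongue LRC 236, tongue against palate 2453, tail minus back 1182 and oral minus skin 361. With the replicate number as a block they were back basal LRC 95, tail LRC 2055, palate LRC 6, tongue LRC 29, granular against spinous 1197, tongue against palate 605, tail minus back 1107 and oral minus skin 202. In the paired comparisons, the LRC effect in tail minus back included, the block moved no other count by over 1.5 times (back spinous LRC 2571 to 3385) and changed no call of a named gene or list. For palate, tongue, bulge and tongue against palate the numbers were not taken to pair libraries, with under 3 pairs or not every correlation over 0.1: 0.0364 to 0.233 for back bulge, −0.0436 to 0.426 for tail bulge, −0.0569 to 0.254 for tongue against palate, 0.283 for palate and 0.0471 for tongue. As a hint from the data, bulge and basal libraries deviated most like their own number in 11 of 12 checks in back and 8 of 12 in tail. By DESeq2 the counts were back basal LRC 219, tail LRC 1335, palate LRC 12, tongue LRC 88, granular against spinous 1218, tail minus back 776 and oral minus skin 126, and by limma on exon TPM back basal LRC 0, tail LRC 446, back spinous LRC 1065, back bulge 1928, spinous against basal 599, granular against spinous 197 and tongue against palate 588. With only the compared groups fitted they were back basal LRC 64, tongue LRC 6, back spinous LRC 3895, back bulge 2769, spinous against basal 2736 and granular against spinous 1555. Back bulge against nLRC alone gave 2728, oral against tail alone 5633, and oral minus skin with all 35 libraries fitted 13. Without single libraries the counts were back basal LRC 2 to 128, tail LRC 342 to 684, palate LRC 0 to 1601, tongue LRC 0 to 45, back spinous LRC 1306 to 4476, back bulge 3907 to 5643, tail bulge 2716 to 3826, spinous against basal 1031 to 2455, granular against spinous 288 to 1590, tongue against palate 700 to 3406, oral against skin 8066 to 9018, tail minus back 345 to 534 and oral minus skin 7 to 39. Where a group of 2 kept 1 library, it was assumed to vary like the other groups. Of list tests 164 passed, 12 with an estimated correlation and 101 by fry. The sign turned for the cell cycle inhibitor list in back spinous LRC with the block (adjusted p = 0.876) and the sort surface list in back bulge by fry (adjusted p = 0.707), neither past its test before, and for H2-Q4 (0.98), Nlrc5 (1.79) and mt-Nd6 (−0.13) in oral against tail alone. Of 5321 values of 323 named gene results under the alternatives 4910 kept direction and side of the threshold, 382 lost the call and 26 gained one. List medians relative to all genes turned for the tongue LRC fibroblast list by DESeq2 (−0.82) and Wnt list on exon TPM (0.00), and, of printed lists short of the test, for muscle in tongue against palate by DESeq2 (0.12) and on exon TPM for T cell genes in oral against skin (0.19) and endothelium in oral minus skin (0.06). The median gene lay over 0.1 from 0 on the log2 scale by DESeq2 (tail LRC 0.33, tongue against palate −0.12, tail minus back 0.25 and oral minus skin −0.10), on exon TPM (tail LRC 0.19, palate LRC 0.18, tongue LRC −0.10, back bulge −0.26, tail bulge −0.15, tongue against palate 0.15, oral against skin −0.64 and tail minus back 0.16), with median-of-ratios scaling (back bulge 0.11), without the low-count filter (tail LRC 0.25, tail bulge −0.17, oral against skin −0.18 and tail minus back 0.29), without palate nLRC 1 (palate LRC 0.16 and oral against skin −0.14), without palate LRC 1 (oral against skin −0.11) and without palate nLRC 2 (tail minus back 0.10). The alternative pseudocounts for normalized values were not run, since the files hold counts. In back basal LRC a change of 1 on the log2 scale was mostly missed on simulated data.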

Other observations

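Reads of Xist, made by the inactive X chromosome, and of Y-linked genes followed the replicate number. Xist had 22764 to 35621 reads and Y-linked genes 1 to 15 in the 6 back libraries numbered 1, against 1 to 20 and 677 to 4703 in those numbered 2 and 0 to 8 and 2458 to 4477 in those numbered 3. In tail the 3 libraries numbered 2 had 5541 to 13368 Xist and 1 to 8 Y-linked reads, those numbered 1 0 to 11 and 1874 to 2449, and those numbered 3 1 to 4 and 1030 to 2209. Palate libraries held both (2910 to 6494 and 1363 to 1981 in number 1, 1428 to 10230 and 209 to 402 in number 2), as did tongue number 1 (2496 to 4268 and 1446 to 1735), while tongue number 2 had 8099 to 12766 and 6 to 7. Of 34 genes lower in back basal LRC libraries and tested in tail, 10 were higher in tail LRC libraries, against 1.13 by chance, and 2 lower, against 0.524.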
